A study of Bubalus bubalis with 2 samples.

How the data were processed

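Testis cells of water buffalo (Bubalus bubalis) were measured by droplet single-cell RNA sequencing on the 10x platform in 2 libraries, 1 from an animal of 3 months and 1 from 24 months, with germline and somatic cells together. Per the file headers, each deposited matrix holds counts: whole numbers of unique molecular identifiers (UMIs) for each gene and cell barcode, written with software version 3.1.0, and the header names no program. The aligner, genome build and cell-calling settings are not given in the sources used here. A second deposited table per library repeats the same counts as genes by barcodes, and all 25836 genes were identical to the matrix in both libraries, so it served for that check alone.

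The files name genes by NCBI identifiers and symbols. Of the 25836 genes, 22027 identifiers were found in the NCBI RefSeq gene table of assembly NDDB_SH_1, which was used for names and for the order of neighbouring genes and gave 186 further symbols. A total of 9381 identifiers (36.3%) stayed without a symbol, and no named gene comes from them. The 3-month file lists 18798 barcodes with 58310660 UMIs, and the 24-month file lists 15632 barcodes with 93883159 UMIs. The lowest barcode of the 3-month file holds 1663 UMIs and that of the 24-month file 500, so the libraries had already been filtered at different depths.

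Cells with at least 200 genes and 500 UMIs and at most 20% of UMIs from the 13 mitochondrial genes were kept, which left 18785 cells at 3 months and 15430 at 24 months. Scrublet, run on each library in scanpy 1.11.5, set thresholds of 0.550 and 0.686 and marked 0 cells in either library, so it was taken as not having worked. In its place the 6% of cells with the highest scores, 1127 and 926, were removed, leaving 17658 and 14504. Both libraries were clustered together without integration: counts were scaled to 10000 per cell and logged, 3000 variable genes were chosen, and 30 principal components and 15 neighbours went into Leiden clustering at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). Genes of the fixed lists other than naming markers (381 in the file) were held out of the clustering. Ligand and receptor genes outside these lists were not held out. Mixed clusters were split at resolution 0.5. A cluster was named after 1 of 17 sets of markers when at least 3 of them were in 10% of its cells at 2-fold or more of the other cells (10 CPM added to both). Clusters stayed unnamed with fewer markers, with more markers of another class among their 10 leading genes, or with a low UMI count and no marker among those genes.

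UMIs were summed over the cells of a class in each library and given as counts per 1000000 of that sum (CPM). Classes with at least 50 cells in both libraries were compared, which held for spermatogonia-like and Sertoli-like cells. Log2 ratios of 24 months over 3 months carry exact conditional binomial 95% intervals, levels carry exact Poisson intervals and shares carry exact binomial (Clopper-Pearson) intervals. These cover counting error alone. With 1 library per age, no test between ages was made and no difference has a replicate check. Genes needed 50 UMIs over both sums, a gene at 0 was set to a floor of 3 counts in its class sum and its ratio given as a bound, and 0 cells of a class was given the upper limit that 3 cells would allow. The 23 gene lists were each described by the median log2 ratio, the members at 2-fold or more in each direction, and the percentile of the median among 10000 random lists matched on size and mean level, which describes these libraries and is no test. Genes per cell were compared after thinning each cell to 1000 UMIs.

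Named genes followed a fixed rule. Per comparison, genes were ranked in each direction by the size of the interval bound of the log2 ratio nearest 0. The 10 highest were named, among genes with a symbol and leaving out ribosomal protein and mitochondrial genes. A gene was passed over where its level was under 10% of its highest class, among classes with at least 50 cells in the library where it was higher. Free RNA could give such a level. Members of the fixed lists, naming markers as a check of the labels, and the 64 ligand and receptor pairs could also be named. For the germ-cell classes at 24 months, the members with the highest levels and those that peaked apart from most of their list were named. A pair was described where ligand and receptor each reached 50 CPM and 10 UMIs in a class with at least 50 cells. In 1 pair a gene was not measured under its symbol, which left 63. The level of 1 list member is not reported here.

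The markers, lists, pairs, filters and the rule for named genes were set before the data were examined, as were the alternatives except those named as added. The alternatives covered the cell filters, doublet removal, clustering resolution, separate clustering, TMM scaling, a minimum of 10 UMIs, subtraction of 5% free RNA, equal weight per cell, and pair levels of 20 and 100 CPM. Intervals and list percentiles were tested on simulated counts with 200 genes set to known ratios. The intervals covered the true ratio for 96.2% of 8323 genes at Sertoli-like depth and 96.0% of 9488 genes at spermatogonia-like depth. The simulated counts held counting error alone, as the intervals assume, so this checks the computation and not differences between real libraries. Of genes simulated with a 4-fold higher level, 100.0% reached 2-fold at both depths, and of those with a 4-fold lower level 97.9% and 100.0% did. Of unaltered genes 3.14% and 0.344% passed 2-fold by counting error. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.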

Results

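Single-cell transcriptomes were compared between the testis of a 3-month-old buffalo, labelled as before puberty, and that of a 24-month-old, labelled as around puberty. The study set out to follow the steps of spermatogenesis and the signals exchanged between testis cells. After filtering, 17658 cells with 52978428 UMIs remained at 3 months and 14504 cells with 85838044 UMIs at 24 months. The median cell of the deposited files held 2560 UMIs and 1125 genes at 3 months and 2712 UMIs and 1512 genes at 24 months. Levels are given in CPM, the UMIs of a gene per 1000000 UMIs of a class. Each age is 1 library, so the values below compare these libraries and have no replicate check.

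The makeup of the 2 libraries differed almost completely. The shares count kept cells of 1 library per age and were not set against cell counts in the tissue. At 3 months stromal fibroblast-like cells made up 60.3% of kept cells (10653 cells, 95% interval 59.6 to 61.1%) and Sertoli-like cells 12.3% (2173 cells, 11.8 to 12.8%). At 24 months the 4 germ-like classes together made up 79.5% (11534 cells, 78.9 to 80.2%). Spermatocyte-like cells reached 30.3% (4391 cells), round spermatid-like cells 20.7% (3004 cells) and elongating spermatid-like cells 25.1% (3640 cells), while none of these classes held any of the 17658 cells at 3 months, which allows a share of up to 0.017%. Spermatogonia-like cells were a similar small share at both ages, 2.77% (490 cells, 2.54 to 3.03%) at 3 months and 3.44% (499 cells, 3.15 to 3.75%) at 24 months. Their order turned with at most 10% mitochondrial UMIs (2.75 and 2.65%) and at resolutions of 0.5 (2.77 and 2.76%) and 2.0 (2.77 and 2.07%).

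Somatic cells were scarce in the older library. Sertoli-like cells made up 1.09% (158 cells, 0.927 to 1.27%) and stromal fibroblast-like cells 0.0207% (3 cells, or 0.614% with the libraries clustered separately), and endothelial-like, macrophage-like and T or NK-like cells numbered 6, 6 and 14. At 3 months these last classes made up 6.68%, 2.56% and 1.22%. A cluster led by INSL3, the hormone of Leydig cells, held 4.02% of cells at 3 months and 1 cell at 24 months, and stayed unnamed because the files hold 2 of the 6 Leydig markers. No cluster took the names of peritubular myoid, pericyte, B, mast, glial, erythroid or duct cells. Such cells may still lie in clusters named after another class. Stromal fibroblast-like cluster 1 (3615 cells at 3 months) had ACTA2 among its leading genes, with 7 stromal and 3 peritubular myoid markers. An endothelial-like cluster of 33 cells at 3 months was led by HIGD1B and RGS5, with 10 endothelial and 8 pericyte markers. Other clusters without a name held 10.1% of cells at 3 months and 19.2% at 24 months. They include clusters with Sertoli genes among their leading genes, 8 and 22 at 3 months (7.45 and 2.67%) and 17 at 24 months (3.90%), and clusters with spermatid or spermatocyte markers, 3.0, 3.2, 5.2 and 24 at 24 months (4.84, 2.59, 1.99 and 2.34%), so the Sertoli-like and germ-like shares would be larger if these were counted. The shares rest on files that begin at 1663 UMIs per barcode at 3 months and 500 at 24 months, and with that same floor in both libraries, an alternative chosen after seeing the data, Sertoli-like cells at 24 months came to 2.06%.

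**Figure D1:**
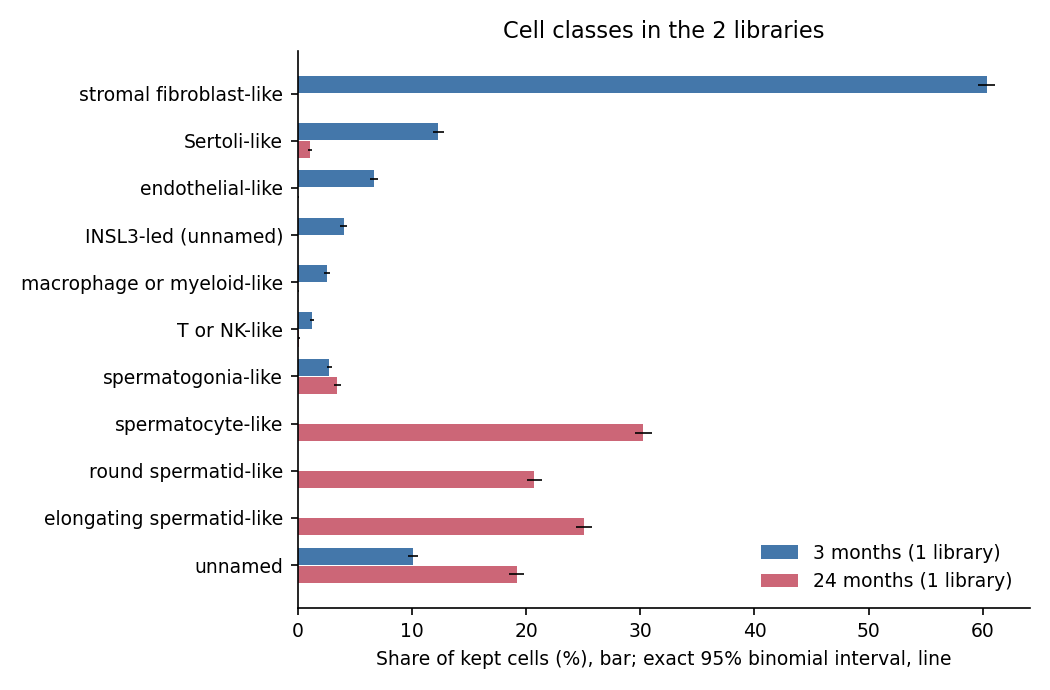
Share of kept cells (%) in each class at 3 months (blue, 1 library) and 24 months (red, 1 library), with exact 95% binomial intervals as lines. Stromal fibroblast-like cells led at 3 months with 60.3% and the germ-like classes together at 24 months with 79.5%.

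Sums over all kept cells, which mix cell makeup with expression, differed in the same way. Every 1 of the 31 measured sperm flagellum genes was at least 2-fold higher at 24 months (median log2 ratio 6.55), as were 14 of 17 acrosome genes (median 7.61) and 10 of 12 genes of germ-cell energy metabolism (median 5.04). The genes that led this direction belong to late spermatids: HSPB9 stood at 0.094 CPM at 3 months and 4292 at 24 months, and P3R3URF and IQCF5 had 0 UMIs at 3 months and at least 25646-fold and 22283-fold higher levels at 24 months. In the other direction stood SOCS3, an inhibitor of cytokine signalling, with 956 CPM at 3 months and 0 UMIs at 24 months (at least 27354-fold higher at 3 months). FOS stood at 8361 against 1.34 and INSL3 at 2794 against 0.839. All 21 extracellular matrix genes were at least 2-fold higher at 3 months (median -5.79), as were all 14 interferon response genes (median -5.52), all 7 antigen presentation genes (median -4.15), 11 of 15 macrophage genes (median -6.02) and 8 of 13 steroidogenesis genes (median -2.98).

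Spermatogonia-like cells, named by markers of stem and differentiating germ cells, were compared to see how their program differs between the ages. At 24 months the class also carried the meiotic marker SYCP3 (340 CPM, against 59.1 in spermatocyte-like cells and 30.6 in this class at 3 months). STRA8 stood at 17.4 CPM at 3 months and 274 at 24 months. Cluster 12.5 had 4 spermatocyte markers, so the ratios may also compare which stages the label covers at each age. Genes of the cell cycle were higher at 24 months: TOP2A, which untangles DNA in dividing cells, stood at 50.3 CPM at 3 months and 478 at 24 months (log2 ratio 3.25, interval 2.99 to 3.51), and MKI67, a marker of cycling cells, at 7.82 and 152 (log2 4.28, 3.66 to 4.97). MKI67 was higher still in elongating spermatid-like cells of that library (824 CPM), whose naming markers were also higher in these cells at 24 months. MEIOC, needed for entry into meiosis, was 17.6-fold higher at 24 months (log2 4.14, 3.54 to 4.78), and the synaptonemal complex gene SYCE2 was 9.64-fold higher (log2 3.27, 2.83 to 3.73). POU5F1, a pluripotency factor, was 17.3-fold higher at 3 months (37.8 against 2.18 CPM, log2 -4.12, interval -6.42 to -2.53). At 3 months 489 of the cells lay in cluster 19, and at 24 months cluster 19 held 45 cells and clusters 12.1, 12.2 and 12.5 held 172, 168 and 114.

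By list, 12 of 22 proliferation genes were at least 2-fold higher at 24 months, 1 (MCM7, log2 -1.29) was higher at 3 months and 9 lay between. The list's median log2 ratio was 1.26, above that of all 10000 random lists. Meiotic recombination genes had a median of 0.69 (percentile 99.6), with 7 of 22 higher at 24 months, among them SYCE2, SYCE3 and REC8, and 2 higher at 3 months, among them TEX15 (log2 -1.06). Of 13 spermatogonial differentiation genes 5 were higher at 24 months, among them CTCFL (2.72 and 90.0 CPM) and DNMT1 (59.9 and 143), and 2 were higher at 3 months, among them CCND2 (log2 -1.70), for a median of 0.63 (percentile 95.2), which was 0.0196 with a minimum of 10 UMIs. Within cluster 19 alone neither CCND2 (108 and 139.5 CPM) nor MCM7 (341 and 350.4) was higher at 3 months. The piRNA pathway had a median of 0.57 (percentile 97.7): DAZL (226 and 501 CPM) and TDRKH were among 5 of 20 members higher at 24 months, and HENMT1 (log2 -1.46) and PIWIL4 (log2 -1.66) were higher at 3 months.

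Stem cell state genes leaned the other way, with 6 of 13 at least 2-fold higher at 3 months and a median of -0.94 (percentile 4.6). These included CD9 (109 and 21.0 CPM), UPP1, and RET and GFRA2, receptors for signals that maintain stem cells, while NGFR (log2 1.09) was the single one of the 13 higher at 24 months. EPCAM and CDH1, on this list but left out of the 13 as naming markers of duct cells, stood at 37.4 and 377 CPM and at 1.36 and 0. Within cluster 19 alone RET (15.7 and 19.5 CPM) and GFRA2 (43.6 and 55.2) were not higher at 3 months, while CD9 (109 and 35.7) was. For RET, GFRA2 and the list's median, given below for that cluster, the difference went with which clusters held the cells, while CD9 still differed. The 24-month side of cluster 19 held 45 cells with 308209 UMIs, so these levels rest on few UMIs. Imprinted growth genes had a median of -1.03 (percentile 0.935), with IGF2 3.01-fold higher at 3 months and PEG10 5.70-fold higher at 24 months. Retinoic acid genes (median -0.68), cholesterol genes (median 0.41), respiratory chain genes (median 0.05), germ-cell chromatin genes (median 0.31) and CREM-related regulators (median 0.22) lay between these. Steroidogenesis, blood-testis barrier, Sertoli maturity and Sertoli immaturity lists had medians of -0.55, -0.21, -0.71 and -2.19 in these cells, and of the macrophage list 1 gene was measured.

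RNA typical of other cells stood beside both directions. Naming markers of elongating spermatids had a median log2 ratio of 8.06 in spermatogonia-like cells (9 of 9 higher at 24 months), those of round spermatids 5.18 (7 of 7) and those of spermatocytes 1.31 (7 of 11, percentile 99.9). The flagellum (median 2.54, 17 of 20 higher), acrosome (median 4.25, 9 of 10) and energy metabolism lists (median 1.82, 6 of 10) were higher with them. The genes that led by the fixed rule at 24 months, HSPB9 (1.70 and 913 CPM, log2 9.07, interval 7.84 to 10.69), SPTY2D1OS, TSSK6, DNAJB8, CETN1, CMTM2, LLCFC1, TBC1D21, C12H9orf50 and FAM187B, each had their highest level in spermatocyte-like or elongating spermatid-like cells, and 29 more had been passed over.

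On the 3-month side, stromal naming markers had a median of -5.17 in spermatogonia-like cells (7 of 7 higher at 3 months), and DCN, a proteoglycan of connective tissue, stood at 532 and 8.71 CPM. The extracellular matrix (median -3.70, 15 of 17 higher at 3 months), stress (median -4.24, 11 of 16) and interferon lists (median -5.40, 3 of 5) were higher with them. The 5 heat shock genes of the stress list went the other way (median 0.70). Antigen presentation genes (median -1.35, 3 of 6) lay at percentile 15.5 of the random lists, so that list was not set apart. The leading genes at 3 months were FOS (1448 and 0.726 CPM, log2 -10.96, interval -16.27 to -8.48), MGP, COL3A1, JUNB, FOSB, SOCS3, ZFP36, ISG15, IFI6 and PTN, each highest in another class, and AMH had been passed over. Stromal naming markers stood at a median of 12.2% of their stromal level in these cells, above the share under which genes were passed over. The rule thus passed over 0 of the 7 stromal markers and 0 of the 17 matrix genes. These leading genes were therefore not told apart from RNA of other cells. In all, 1861 of 9878 genes were at least 2-fold higher at 24 months and 1966 at 3 months. Cluster 19 alone was an alternative chosen after seeing the data. There TOP2A stood at 50.4 and 136 CPM, MKI67 at 7.83 and 38.9, MEIOC at 8.85 and 32.5 and POU5F1 at 37.8 and 6.49. These were smaller differences than over the whole class. The 24-month levels rest on 45 cells with 308209 UMIs, of which MKI67 had 12 (interval 20.1 to 68.0 CPM) and TOP2A 42. TNP1 stood at 597 CPM there and 11135 in elongating spermatid-like cells, so MKI67 of these cells was not told apart from spermatid RNA. In that cluster the proliferation median was 0.24, that of the differentiation list 0.11 and that of the stem cell list -0.0451. After thinning to 1000 UMIs the median cell held 758 genes at 3 months and 804 at 24 months, with 126 shallower cells left out at 24 months, against 2377.5 and 1533 before thinning.

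**Figure D2:**
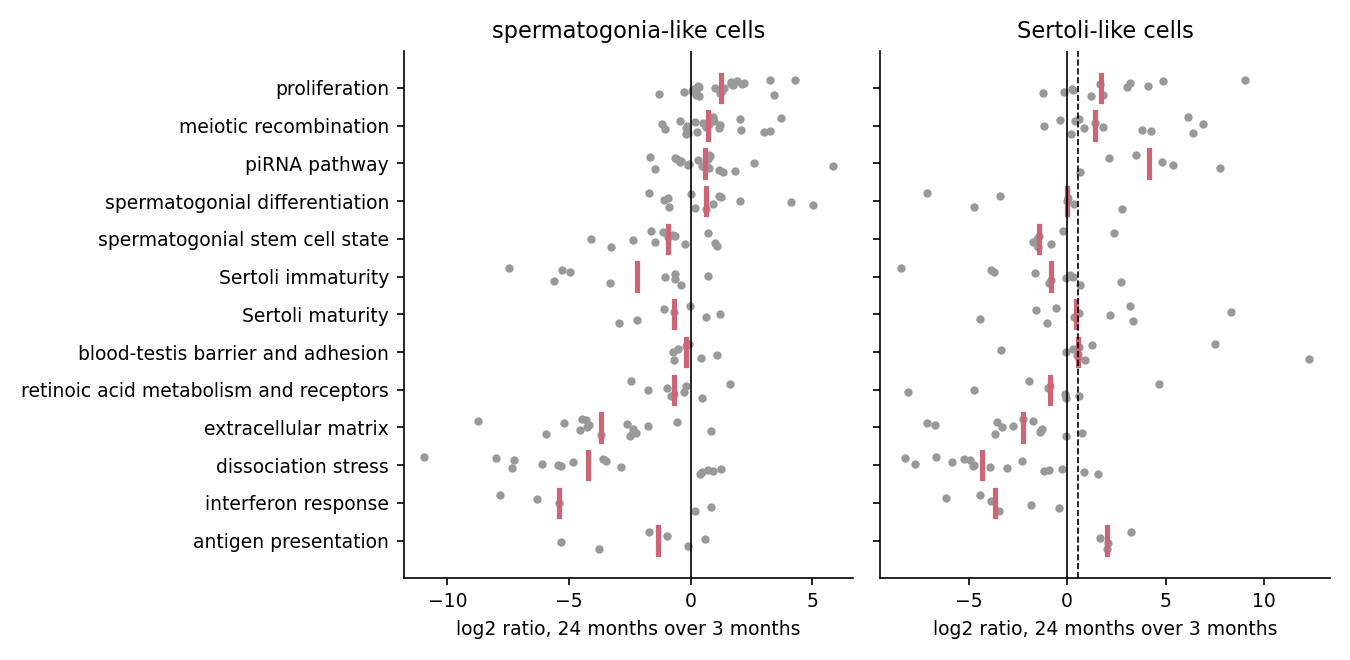
Log2 ratios of 24 months over 3 months for the measured genes of fixed lists (grey points) and list medians (red bars) in spermatogonia-like and Sertoli-like cells, with a solid line at 0 and a dashed line at the Sertoli-like median of all genes, 0.557. Stress and extracellular matrix medians lay below 0 in both classes, and the Sertoli maturity and blood-testis barrier medians turn below 0 under TMM scaling (-0.32 and -0.21).

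Sertoli-like cells, which nurse the germ cells, were compared to see how they differ across puberty. The hormone AMH, secreted by immature Sertoli cells, stood at 8884 CPM at 3 months (interval 8815 to 8953) and 25.5 at 24 months (16.4 to 38.0), a 348-fold difference. INHA, a subunit of inhibin, was 14.7-fold higher at 3 months (12243 and 835). Of 11 genes of the blood-testis barrier and adhesion, 2 were at least 2-fold higher at 24 months relative to all genes. CLDN11, a tight junction protein, stood at 3.63 and 653, and ESPN, which bundles actin at Sertoli junctions, had 1 UMI at 3 months and 701 CPM at 24 months (log2 12.30, interval 9.81 to 17.60). RARRES1, a gene that responds to retinoic acid, had the highest rank of any gene with its peak in Sertoli-like cells at 24 months (0.698 and 2077). The 3-month cells lay in clusters 7 (1436 cells) and 14 (737 cells), and the 24-month cells formed cluster 29.

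The median log2 ratio of all measured genes in this class was 0.557, and TMM scaling set the libraries 0.783 log2 units apart. In the next paragraphs on this class ratios have this median taken off, except where they are said to be without the shift. At least 2-fold higher without that shift were 3215 of 9061 genes at 24 months and 1288 at 3 months, and under TMM scaling 1574 and 2417.

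Of 11 Sertoli immaturity genes, 6 were at least 2-fold higher at 3 months, among them AMH (relative log2 -9.0, interval -9.64 to -8.43), INHA (-4.43), VIM (-1.48) and KRT8, which had 0 UMIs at 24 months, and GJA1, a gap junction gene, was higher at 24 months (2.16). The list's relative median was -1.36, at percentile 1.82 of the random lists. Without the shift it was -0.80, and -0.42 with a minimum of 10 UMIs, -1.58 under TMM scaling, -1.75 with an unnamed cluster led by Sertoli genes added and -1.96 with libraries clustered separately. Sertoli maturity genes went both ways (relative median -0.09, percentile 24.1): the water channel AQP8 (15.8 and 162 CPM, relative log2 2.80), the lactate transporter SLC16A1 (1.63) and PRND were among 4 higher at 24 months, and RBP4 (-4.97, -7.25 to -3.42) and GATA4 (-1.60) were among 4 higher at 3 months. Without the shift this list's median was 0.46, and it fell below 0 under TMM scaling (-0.32), with libraries clustered separately (-0.89) and with an unnamed cluster led by Sertoli genes added (-0.49). Blood-testis barrier genes had a relative median of 0.02, with CLDN11 (6.94) and ESPN (11.74) higher at 24 months, CXADR (-3.90, -6.19 to -2.33) higher at 3 months and 8 between. Their median without the shift, 0.58, turned to -0.21, -0.0525 and -0.25 under those same alternatives.

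**Figure D3:**
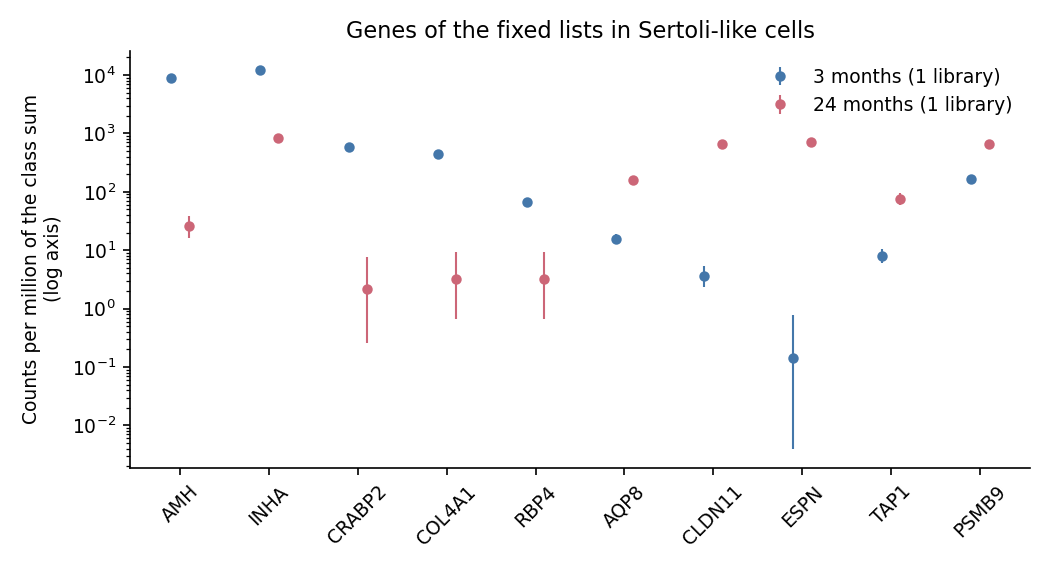
Levels of fixed-list genes in Sertoli-like cells (CPM, log axis) at 3 months (blue, 1 library) and 24 months (red, 1 library), with exact 95% Poisson intervals. AMH stood at 8884 and 25.5, and CLDN11 at 3.63 and 653.

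Retinoic acid genes were lower at 24 months as a list (relative median -1.43, percentile 0.2, 5 of 9 members). CRABP2, a carrier of retinoic acid, stood at 576 and 2.13 CPM, STRA6, a receptor for retinol uptake, at 85.7 and 3.19, and ALDH1A1, which makes retinoic acid, at 634 and 163. ALDH1A3, another such enzyme, stood at 1.68 and 42.6. Extracellular matrix genes had a relative median of -2.78 (11 of 13 higher at 3 months), led by the basement membrane collagens COL4A1 (444 and 3.19) and COL4A2 (223 and 2.13), with stromal naming markers at -2.79 (4 of 4). Of the 13 matrix genes, 6 stood low enough against their highest class for free RNA to give that level, as did all 4 stromal markers. The list's median was therefore not told apart from free RNA. Imprinted growth genes had a relative median of -2.04, with IGF2 (-3.87, -6.16 to -2.31) and PEG3 (-3.97, -5.60 to -2.74) among 4 of 6 higher at 3 months. Of these 6 imprinted genes, 2 stood low enough against their highest class for free RNA to give that level. At 3 months IGF2 reached the level set for pairs in stromal fibroblast-like cells but not in Sertoli-like cells. Most interferon genes (-4.22, 5 of 6) and stress genes (-4.88, 13 of 16) were higher at 3 months, while HSP90AA1 (725 and 2139) was higher at 24 months and the rest lay between. All 4 measured antigen presentation genes were higher at 24 months (relative median 1.47), among them the peptide transporter TAP1 (8.09 and 76.6) and the immunoproteasome subunit PSMB9 (163 and 652).

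Proliferation genes had a relative median of 1.18 (percentile 99.1), with 7 of 12 higher at 24 months, among them BIRC5 (3.21 and 94.7 CPM) and TPX2, and MCM7 higher at 3 months. Of the 12, 3 stood under 10% of their highest class, a level free RNA could give. Without the shift the median was 1.74, and it was lower under TMM scaling and higher with libraries clustered separately. Germ-cell lists stood beside them, with the members at least 2-fold higher at 24 months: flagellum (relative median 6.25, 11 of 12), piRNA (3.60, 5 of 6), energy metabolism (1.82, 5 of 9), acrosome (1.08, 4 of 8), meiotic recombination (0.86, 6 of 13), CREM-related regulators (0.72, 4 of 10) and germ-cell chromatin (0.35, 1 of 7). Naming markers of elongating spermatids were higher in Sertoli-like cells at 24 months by 9.61 (9 of 9) and those of round spermatids by 7.42 (4 of 4). Stem cell state (-1.99), differentiation (-0.56), steroidogenesis (-0.42), cholesterol (-0.33) and respiratory chain genes (-0.12) lay lower, and of 3 macrophage genes MRC1, with 1 UMI at 3 months and 200.1 CPM at 24 months, was higher at 24 months.

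By the fixed rule, the leading genes at 3 months after AMH were PCOLCE2 (926 and 1.06 CPM), CCL25 (681 and 2.13), FOSB, CRABP2, FOS, MYL9, MMP23B, MFAP2 and IFI6 (1839 and 25.5). At 24 months they were HSPB9, GSG1, RARRES1, DNAJB8, C14H20orf144, OAZ3, C24H16orf82, ESPN, SPTY2D1OS and P3R3URF, and of these RARRES1 and ESPN were highest in Sertoli-like cells and the other 8 in elongating spermatid-like cells. The median Sertoli-like cell held 2856 UMIs at 3 months and 6023.5 at 24 months, and 517 and 728.5 genes after thinning to 1000 UMIs, against 1135 and 2680 before, with 0 cells left out at either age.

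The germ-like classes at 24 months trace the order of spermatogenesis, and the fixed lists show which programs each class carried. Flagellum genes summed to 2540 CPM in spermatogonia-like, 9556 in spermatocyte-like, 14214 in round spermatid-like and 16217 in elongating spermatid-like cells, and 21 of 31 members peaked in a spermatid-like class. TPPP2 (3673 in elongating spermatid-like cells), SPA17 (3161) and ODF2, of the outer dense fibres (2450), led, while ROPN1 peaked in round spermatid-like cells (2933) and DNAI2, a dynein of the axoneme, in spermatocyte-like cells (519). Genes of germ-cell energy metabolism went from 1035 through 2203 and 4141 to 6231. GAPDHS, a glycolytic enzyme of sperm, reached 2712 and HK1 844 in elongating spermatid-like cells, PDHA2 peaked in round spermatid-like cells (760.4) and PGK2 in spermatocyte-like cells (807).

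Meiotic recombination genes summed to 2771 in spermatogonia-like and 2794 in spermatocyte-like cells and to 1392 and 880.1 in round and elongating spermatid-like cells. Of 24 members 15 peaked in spermatogonia-like cells, among them MND1 (256), TEX11 (239) and BRCA2 (204), as did the spermatocyte naming markers SYCP3 and SPO11, and 8 in spermatocyte-like cells, among them SMC1B (554), SYCE2 (485) and SYCE3 (476). RNF212, which marks crossover sites, was the single member that peaked after meiosis (495 in elongating spermatid-like cells). These peaks compare class sums, in which cells with more UMIs weigh more. Spermatocyte-like clusters 13 and 20 held a median of 18216 and 22045 UMIs per cell, against 1077.5 in cluster 12.3. TEX11 was among the leading genes of cluster 12.3, and SYCP3 among those of other spermatocyte-like clusters. The class with the peak may therefore not hold the cluster with the highest level. Spermatogonia-like cluster 12.5 had 4 spermatocyte markers, so that class may also hold cells that enter meiosis. Of 19 piRNA genes 3 peaked after meiosis, MAEL (198) and GTSF1 (1892) in round and GTSF1L (728) in elongating spermatid-like cells, and DAZL peaked in spermatogonia-like cells (501). Acrosome genes summed to 5683 in round spermatid-like cells, where CALR3 peaked (2335), while IZUMO4 peaked in spermatocyte-like cells (2430) and CYLC2 in elongating spermatid-like cells (912). CREM-related regulators were highest in spermatocyte-like cells (5823), with YBX1 (2104), PABPC1 (1702) and YBX2 (1137) peaking there and CREM (358) and FHL5 (556) in round spermatid-like cells. HSPA2 (586) peaked in spermatocyte-like cells and CHD5, a chromatin remodeller of histone exchange, in round spermatid-like cells (387).

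Proliferation genes were highest in spermatogonia-like cells (4826 in sum, against 3273, 934 and 1056). TOP2A went from 478 to 5.95 CPM, whereas MKI67 was the single member of 22 that peaked after meiosis, at 152 in spermatogonia-like, 32.0 in spermatocyte-like, 455 in round spermatid-like and 824 (interval 813 to 836) in elongating spermatid-like cells. By cluster the order of the first 2 classes was mixed. TOP2A stood at 853 CPM in spermatocyte-like cluster 12.3 and 616 in spermatogonia-like cluster 12.1, and CENPF at 704 and 1052. Spermatogonial differentiation genes summed to 2013, 810.5, 201 and 169, and stem cell state genes to 771, 188, 229 and 188. Respiratory chain genes summed to 4223, 5048, 2154 and 969, with NDUFB2 highest in spermatocyte-like cells (2240). Among stress genes, HSPA8, a constitutive chaperone, went from 1262 in spermatogonia-like to 3.52 in elongating spermatid-like cells, and HSP90AA1 was highest in spermatocyte-like cells (5497).

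**Figure D4:**
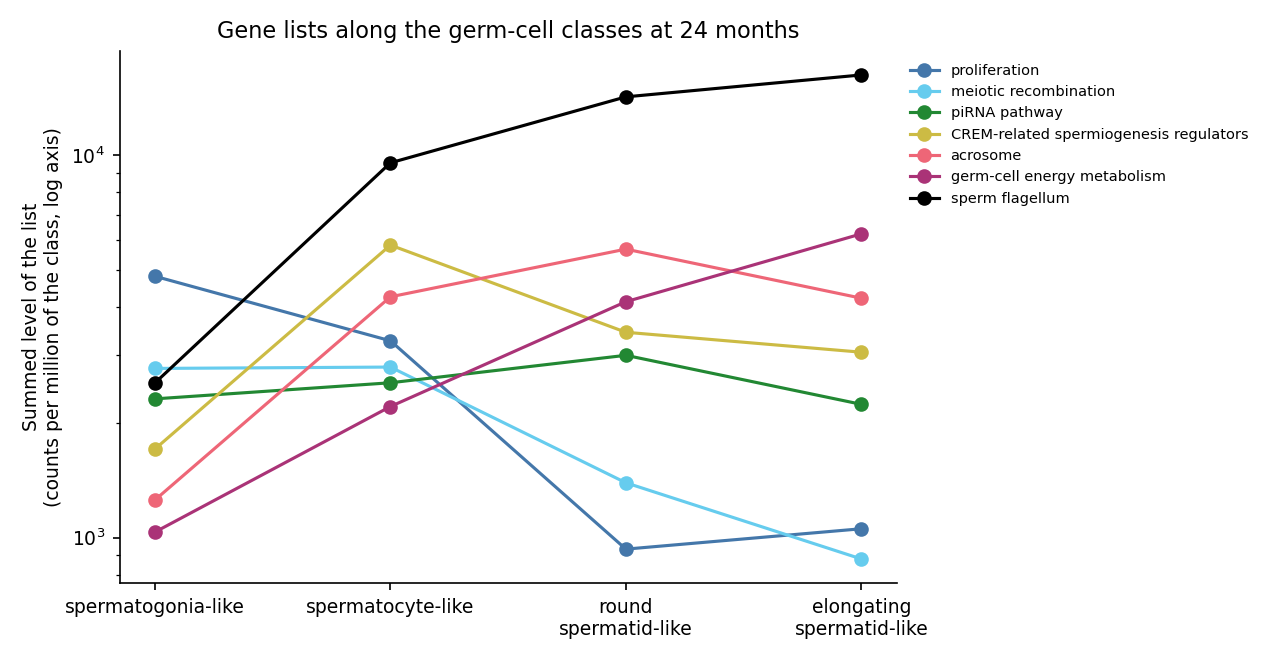
Summed levels of fixed gene lists (CPM, log axis) in the germ-like classes of the 24-month library. The flagellum list climbs from 2540 in spermatogonia-like to 16217 in elongating spermatid-like cells, and the proliferation list stands at 4826 in spermatogonia-like cells and 1056 in elongating spermatid-like cells.

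Ligands and receptors were compared to see which signals the classes could exchange at each age. Of 63 pairs, 23 reached the set level at 3 months and 7 at 24 months, and 3 did so at both ages. At 3 months Sertoli-like cells carried PDGFA (158 CPM) and stromal fibroblast-like cells its receptor PDGFRA (485). Stromal cells carried the chemokine CXCL12 (51.2), with CXCR4 in T or NK-like (342) and macrophage-like cells (268), and VEGFA (62.3), with its receptor KDR in endothelial-like cells (186). They also carried RBP4 (343), the carrier of retinol, with its receptor STRA6 in Sertoli-like cells (85.7), and JAG1 was highest in the INSL3-led cluster (151) with NOTCH2 in stromal cells (105). AMH was far highest in Sertoli-like cells (8884), which also carried AMHR2 (74.4 and 77.7 at the 2 ages), but it passed the level in every other class with at least 50 cells at 3 months too, 468 in endothelial-like cells among them.

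Of the 7 pairs at 24 months, 3 were of cell contact (JAM2 with JAM3, NECTIN2 with NECTIN3 and CADM1 with itself) and 4 had secreted ligands. JAM2 (117) and JAM3 (190.5) were highest in Sertoli-like cells, with JAM3 also at 89.3 in spermatogonia-like cells, and NECTIN2 in Sertoli-like cells (79.8) stood against NECTIN3 in spermatocyte-like (53.0) and round spermatid-like cells (54.5). GAS6 (206) and its receptor TYRO3 (117) were highest in Sertoli-like cells, and MDK (157) and PTPRZ1 (55.9) in spermatogonia-like cells. Both ages had IGF2 with IGF1R, MDK with SDC2 and CADM1 with itself. CADM1, an adhesion molecule, stood at 293 in Sertoli-like and 124 in round spermatid-like cells at 24 months. KIT was in spermatogonia-like cells at both ages (83.7 and 78.4), but its ligand KITLG stayed at 6.84 and 11.7 in Sertoli-like cells, under the level set. Endothelial, immune and stromal classes held fewer than 50 cells at 24 months and could not enter there. With a level of 100 CPM, 9 pairs were left at 3 months, and with 20, 15 pairs entered at 24 months.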

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

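The tests on immediate-early genes were chosen only after the result was seen. The list of antigen presentation genes had a median log2 ratio of 2.03 in Sertoli-like cells (higher at 24 months) and -1.35 in spermatogonia-like cells (higher at 3 months), opposite directions in the 2 classes, and the difference between the classes was not tested. In spermatogonia-like cells 4 of the 6 measured genes stood under 10% of their highest class, a level free RNA could give, and the median lay at percentile 15.5 of the random lists. In Sertoli-like cells this held for 0 of 4 genes. These medians are without the Sertoli-like shift of 0.557, and relative to it the Sertoli-like median was 1.47. PSMB8, an immunoproteasome subunit, stood at 13.8 and 57.5 CPM in Sertoli-like cells at 3 and 24 months and at 28.9 and 0.726 in spermatogonia-like cells.

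Strong signals also lay in clusters that entered no comparison, far above what a count of 0 would allow. INSL3 reached 47833 CPM in cluster 15, nearly all of it 3-month cells. AMH reached 5619 in cluster 8 and 4829 in cluster 22, all or nearly all of 3-month cells, with median doublet scores of 0.109 and 0.136. FATE1, a Sertoli naming marker, reached 4737 in cluster 17 of the 24-month library, which held 566 cells with a median of 1357.5 UMIs and the spermatid gene TNP2 at 17726.

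Late spermatid transcripts (48 genes at 1000 CPM or more in elongating spermatid-like cells and almost unmeasured at 3 months) made up 2.21% of UMIs in Sertoli-like and 1.47% in spermatogonia-like cells at 24 months, against 16.8% in elongating spermatid-like cells. Of these genes 93.8% in Sertoli-like and 100% in spermatogonia-like cells kept within 2-fold of their proportions in elongating spermatid-like cells, which is consistent with RNA of spermatids rather than transcripts the cells made. Free RNA at one amount per droplet may account for it in spermatogonia-like cells, where the lower quartile of such UMIs per cell was 0.677 times the upper quartile of 29 other somatic cells, and for part of it in Sertoli-like cells, where that ratio was 0.978 but the median was 53.5 UMIs against 30 and the upper quartile 153.8 against 34.0. Droplets with a spermatid beside a Sertoli cell could add to it, since the lower quartile of the share per cell was 0.297 of its mean and a minority of cells held much of it. All of these stay open, and age and uptake of spermatid remnants by Sertoli cells were not tested.

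Immediate-early genes, such as FOS and JUNB, were higher at 3 months for all 11 members in both classes, with medians, without that shift, of -4.91 in Sertoli-like and -5.47 in spermatogonia-like cells. RNA of stromal cells in the same droplets is argued against for Sertoli-like cells, since these genes stood at a median of 29.7% of their stromal level and stromal naming markers at 1.61%, a ratio of 18.5. In spermatogonia-like cells the medians were 13.5% and 12.2%, a ratio of 1.10, so stromal RNA may account for the immediate-early genes there. Tissue handling and age cannot be told apart, because each age is 1 library. Heat shock genes of the same list had a median of -0.27 in Sertoli-like cells and 0.70 in spermatogonia-like cells, and no other library could be set against them.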

How the results depend on the processing

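The tests with 1 UMI floor for both libraries, with the shared spermatogonia-like cluster alone, with the unnamed Sertoli-led cluster added and with scaling to genes not dominated by germ cells were chosen only after the result was seen. No paired analysis was possible because each age has 1 library. The Sertoli maturity and blood-testis barrier medians turned below 0 under several settings. The order of the spermatogonia-like shares, 2.77% at 3 months and 3.44% at 24 months, also turned, to 2.75% and 2.65% with at most 10% mitochondrial UMIs, 2.77% and 2.76% at resolution 0.5, and 2.77% and 2.07% at resolution 2.0. Sertoli-like medians in this part are without the shift of 0.557, and the main values on that scale were -0.80 for immaturity, 0.46 for maturity, 0.58 for the barrier and 1.74 for proliferation. The cause was not tested except where the setting itself alters which cells or genes enter.

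Requiring 500 genes and 1000 UMIs gave, at 24 months, 95% germ-like, 57.5% spermatid-like, 3.02% spermatogonia-like and 2.40% Sertoli-like cells, and a Sertoli immaturity median of -1.03. At most 10% mitochondrial UMIs gave 84.6%, 53.1%, 2.65% and 1.82% for those shares. The shared UMI floor gave 88.8%, 51.9%, 3.02% and 2.06%. Resolution 0.5 gave 73.8%, 39.6%, 2.76% and 1.96%, with 14.9% Sertoli-like and 59.0% stromal cells at 3 months, and resolution 2.0 gave 74.0%, 42.8%, 2.07% and 1.42%, with 14.8% Sertoli-like cells at 3 months. Keeping doublets gave 11.6% Sertoli-like and 57.3% stromal cells at 3 months. With the libraries clustered separately, the 24-month shares were 72.1%, 54.4%, 3.12% and 1.39% with 0.614% stromal cells, and the 3-month library had 14.8% Sertoli-like and 43.6% stromal cells. That setting also gave medians of 0.88 for spermatogonial differentiation, -1.96 for Sertoli immaturity, -0.89 for maturity, -0.0525 for the blood-testis barrier and 3.81 for proliferation in Sertoli-like cells, with 2290 genes at least 2-fold higher at 3 months in that class.

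TMM scaling gave 1574 genes higher at 24 months and 2417 at 3 months in Sertoli-like cells, and medians of -1.58 for immaturity, -0.32 for maturity, -0.21 for the barrier and 0.96 for proliferation. Adding the unnamed Sertoli-led cluster gave -1.75, -0.49 and -0.25 for immaturity, maturity and barrier. A minimum of 10 UMIs, which lets more genes enter, gave 3194 and 3772 genes higher at 24 and 3 months in spermatogonia-like cells and 5465 at 24 months in Sertoli-like cells, with medians of 0.0196 for differentiation, -0.42 for Sertoli immaturity and 2.78 for Sertoli proliferation. The shared cluster alone, with 45 cells at 24 months, gave 725 genes higher at 24 months and medians of 0.24 for proliferation, -0.0451 for stem cell state and 0.11 for differentiation. Weighting cells equally gave 0.81 for differentiation and 2 meiotic recombination genes that peaked after meiosis. A level of 100 CPM left 9 pairs at 3 months, and 20 gave 15 at 24 months.

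Subtracting 5% free RNA moved 0 of 19 such values, and scaling to genes not dominated by germ cells moved 0 of 6. The 5% setting cannot show what a larger share of free RNA would do. At 3 months DCN stood at 532 CPM in spermatogonia-like cells and 2661 over all kept cells. Among single genes and the remaining lists, the shared cluster moved 18 of 33 values, TMM scaling 20 of 77 and separate clustering 12 of 78. Subtracting 5% free RNA moved 7 of them and left 69. The counting limits are the 158 Sertoli-like cells with 939716 UMIs at 24 months, and the 499 spermatogonia-like cells with 1377795.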

Other observations

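The test of droplets holding a dividing cell for MKI67 was chosen only after the result was seen. At 3 months the steroidogenesis list summed to 1778 CPM in the INSL3-led cluster and 1678 in macrophage-like cells, where NR4A1 (794) and TSPO (715) made up most of it. STAR, which brings cholesterol into mitochondria, stood at 370 CPM in the INSL3-led cluster and at most 4.46 in any other class, and FDX1 (419), FDXR (263), NR5A1 (215) and the luteinizing hormone receptor LHCGR (444) were also highest in that cluster. Cholesterol synthesis and uptake genes summed to 2553 CPM in it against 727 in macrophage-like cells, the next class, with MSMO1 at 509, HMGCS1 at 249 and SQLE at 214. ALDH1A1, an enzyme that makes retinoic acid, reached 2816 in the cluster against 634 in Sertoli-like cells, and APOE 2842 against 475 in stromal cells.

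Macrophage-like cells at 3 months carried antigen presentation genes, led by CD74 (8665 CPM) and CTSS (1625), beside FOLR2 (301) and F13A1 (243) of resident macrophages and the inflammatory cytokines IL1B (172) and TNF (123). LYVE1 (171) and STAB1 (340), both on the macrophage list, were higher in endothelial-like than in macrophage-like cells (3.38 and 81.2). Stromal fibroblast-like cells had the highest sum of extracellular matrix genes (12842) and of imprinted growth genes (2395), with IGF2 at 1733 and the activin subunit INHBA at 738 against 333 in Sertoli-like cells. At 24 months GDNF, known as a Sertoli signal to stem cells, was highest in round spermatid-like cells (32.3, interval 29.0 to 35.8), against 2.13 (0.26 to 7.69) in Sertoli-like cells. These genes were chosen after their values were seen.

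MKI67, a protein of dividing cells, was highest in elongating spermatid-like cells at 24 months (824 CPM), and it exceeded 350 in each spermatid-like cluster. Droplets with a dividing cell beside a spermatid are argued against: the other 21 proliferation genes stood at a median of 4.22% of their spermatogonia-like level in elongating spermatid-like cells, and MKI67 at 541%. Reads of a neighbouring gene counted as MKI67 cannot be told apart from its own, because neither gene directly beside it in the reference order was measured here, although the measured ones further out reached at most 0.0869 CPM. A transcript of MKI67 that spermatids make may explain the level, and no test of that was possible with these values.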
